A study of Mus musculus with 25 samples.

How the data were processed

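Messenger RNA of mouse pancreatic islets was sequenced as paired-end reads on the BGISEQ-500, and per the labels each islet sample was pooled from at least 3 mice. The labels name 25 samples in 10 groups, of which 19 samples in 8 groups have expression values in 4 deposited tables. The flox/flox and BcBKO samples on chow, 3 each, have no value column and were not analysed here. Per the labels the diets lasted 3 months. Sample numbers in the column names were matched to the labels, and 0 value columns were left without a sample.

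The authors deposited FPKM (fragments per kilobase of transcript, scaled to library size) for all 19 libraries, and TPM (a transcript share scaled to library size) as well for the 4 HFD libraries. The deposited TPM leave genes out and do not add up to the full scale in a library. The authors also deposited their own log2 fold changes with p-values and adjusted p-values for 4 comparisons. These came from DESeq2 per the file headers of the PBS and db tables, and no tool is named for the HFD table. The processing notes name the genome build GRCm38.p6, while the aligner and the counting program are not named. Read counts were not analysed here, so the sequencing depth of each library is unknown and no counting interval or detection floor was computed. Among the lines of the WT libraries, 275 lack a value in at least 1 library and 50 identifiers repeat an earlier one.

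Genes were taken by the Entrez identifier of each table. Expression was analysed as log2(FPKM + 1) for genes with at least 1 FPKM in at least 2 libraries of the table, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend), all groups of a table in 1 fit. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested in a comparison and a threshold of 0.05. Each of the 5 comparisons set 2 libraries against 2, and residual degrees of freedom were 2 in the HFD and db tables and 3 in the PBS table. In 2 comparisons of the PBS table the median gene shifted by over 0.1 on the log2 scale. There the values were also divided by each library's median ratio to the geometric mean library (median scaling), and changes are given relative to that scale. Both scales were tested in every comparison. In the report the counts of list members for those 2 comparisons are after median scaling unless said otherwise, while the p-values of the list tests are on the deposited scale in all comparisons.

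The fixed lists were beta cell identity and glucose sensing, insulin granule exocytosis, other islet hormone cells, dedifferentiation and beta cell disallowed genes, acinar cell, REG family, duct cell, endothelial cell, stellate cell and extracellular matrix, immune cell, inflammation, interferon response, JAK-STAT3 response, unfolded protein response, antioxidant response, oxidative phosphorylation, glycolysis, cholesterol synthesis, lipogenesis, proliferation, apoptosis and p53, and SWI/SNF subunits. These 22 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 5 tested members. An estimated correlation and limma's fry were the alternatives. With an estimated correlation camera also tests on the residual degrees of freedom of the fit, here 2 or 3. A call can therefore be lost without a higher correlation. The 6 acinar, duct, endothelial, stellate, immune and other hormone lists mark cell types other than beta cells.

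Named genes followed a rule fixed, like the lists, groups, tests and alternatives not said to be chosen later, before the data were examined. Smarcd3, Reg3b, Ins1, Ins2, Gcg and Prss2 were always named. Beside them stood the 8 higher and 8 lower genes with the largest change among those past the threshold with at least 5 FPKM in the higher group and no overlap between groups, filled by smallest p where fewer passed, predicted genes left out. The rule added up to 4 passing members of each list, or up to 2 by smallest p where none passed. Zfp423 and the members of the REG family were followed into all comparisons after their values were seen.

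The fit was tested on simulated data with the spread of each table and 50 changed genes at each size. At a 2-fold change it recovered 2% of changed genes in the HFD table and 96 to 100% in the comparisons of the PBS and db tables. At a 4-fold change it recovered 84% in the HFD table and 100% in the other tables. Recovery was not broken down by expression level, so these shares are not read as the recovery of genes of low FPKM. For such genes the pseudocount shrinks a change on the log2 scale. Replicate differences of the HFD groups correlated at 0.669, and how this bears on the HFD recovery was not tested. Unchanged genes made up 8.51% of the simulated calls on HFD and 8.89% for KO_REG3B-Fc against KO_PBS, above the nominal 5%. Alternatives were no filter, a pseudocount of 0.1, median scaling, leaving out each library in turn, replicate number as a block, and only the libraries of the 2 groups in the PBS table. TPM in place of FPKM, a rescaling to an equal sum without acinar and REG genes, the same rescaling with all genes kept, and list tests after median scaling or without each library were chosen after seeing the data. Changes of 3 pairs of comparisons were correlated across genes, which are not independent replicates. Descriptive values and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A p-value here measures spread between libraries of a group, which may be technical, since the labels do not say whether replicates came from separate islet preparations.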

Results

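The data are FPKM values of islet messenger RNA from 19 libraries in 4 tables. The HFD table holds 2 flox/flox and 2 BcBKO libraries from mice on a high-fat diet (HFD). Per the labels, BcBKO stands for a beta-cell-specific ablation with Pdx1-cre, in a study of BAF60C, the SWI/SNF subunit encoded by Smarcd3. The PBS table holds 2 CTR_PBS, 2 KO_PBS and 2 KO_REG3B-Fc libraries, and the labels do not spell out which gene KO refers to. REG3B is a secreted lectin encoded by Reg3b, and Fc is taken to be an antibody tail fused to it. The db table holds 2 db_GFP and 2 db_REG3B libraries, and the WT table holds 5 libraries. Values after ± are SDs, with n = 2 libraries per group unless another n is given. Between 10455 and 12553 genes per library had at least 1 FPKM, and the depth behind these values is unknown.

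The shares of insulin and digestive enzyme transcripts differed between libraries. Ins1 and Ins2 together took 57.6 to 67.8% of summed FPKM in the HFD libraries, 57.5 and 58.4% in CTR_PBS, 38.9 and 38.2% in KO_PBS, and 58.1 and 57.7% in KO_REG3B-Fc. The acinar list, which holds digestive enzymes of the exocrine pancreas, took 19.8 and 19.6% in CTR_PBS, 40.2 and 41.4% in KO_PBS, and 17.0 and 17.2% in KO_REG3B-Fc. On HFD its share was 2.64 and 9.55% in flox/flox and 3.99 and 3.92% in BcBKO. In db libraries it stayed at 0.158% or less, while insulin took 34.6 and 35.0% in db_GFP against 54.7 and 55.0% in db_REG3B. Replicates lay close together in the PBS and db tables, where the robust SD of the log2 ratio between replicates was 0.0484 to 0.0935 for genes of at least 100 FPKM. It was 0.288 and 0.285 in the HFD groups and 0.0938 to 0.920 between WT libraries.

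**Figure D1:**
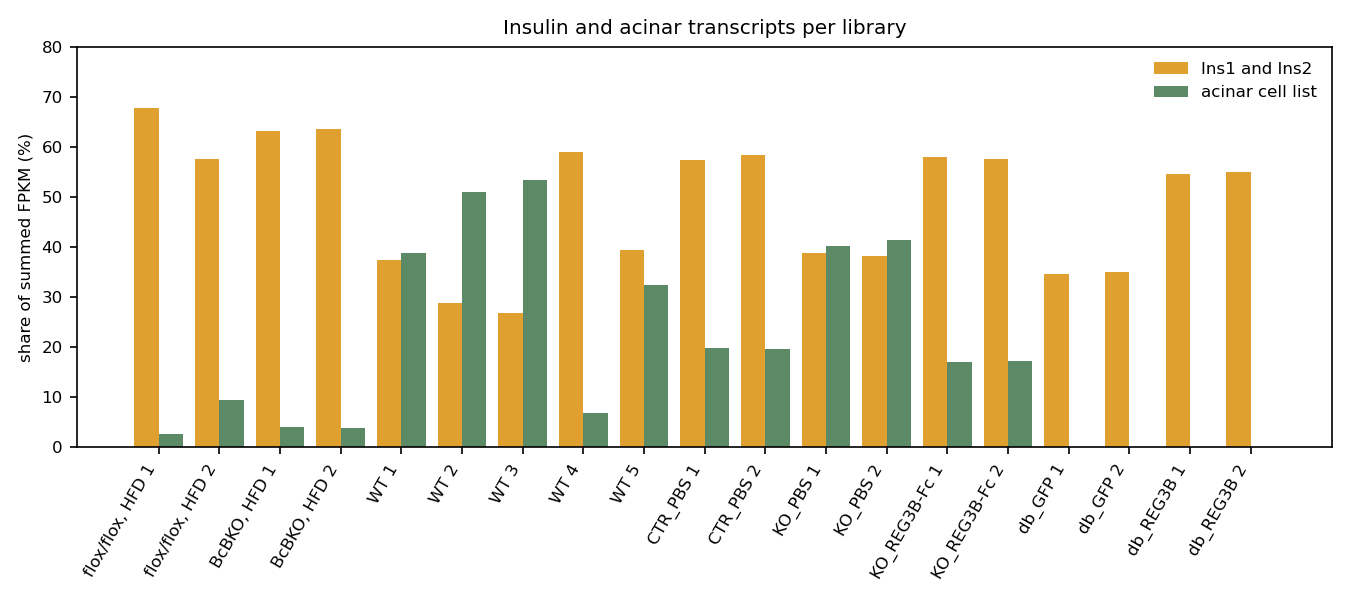
Share of summed FPKM (percent, vertical axis) taken by Ins1 and Ins2 and by the acinar list in each of the 19 libraries (horizontal axis, group and replicate). The acinar bars reach 40.2 and 41.4% in KO_PBS and 19.8 and 19.6% in CTR_PBS.

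Smarcd3 (Entrez 66993, GRCm38.p6 chromosome 5, 24592622 to 24624456, protein coding) was low in every library. It measured 2.57 and 2.55 FPKM in flox/flox and 3.11 and 2.40 FPKM in BcBKO on HFD. In the PBS table Smarcd3 measured 1.03 and 1.15 FPKM in CTR_PBS, 0.75 and 1.09 FPKM in KO_PBS, and 1.28 and 1.21 FPKM in KO_REG3B-Fc. The WT libraries gave 0.84, 0.57, 0.75, 1.71 and 0.99 FPKM. In the db table Smarcd3 fell from 3.18 and 2.61 FPKM in db_GFP to 1.29 and 1.61 FPKM in db_REG3B (log2 change -0.67, adjusted p = 0.00102). Neither knockout comparison passed for Smarcd3, with log2 changes of 0.07 (adjusted p = 1.000) on HFD and -0.13 (adjusted p = 0.207) for KO_PBS, where median scaling turned the sign to 0.14. For KO_REG3B-Fc against KO_PBS, Smarcd3 passed on the deposited scale (0.23, adjusted p = 0.0339) and not after median scaling (-0.10, adjusted p = 0.460). Gene-level FPKM of whole islets does not show whether a floxed exon was deleted or which cells hold the transcript, so group names below are those of the labels.

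**Figure D2:**
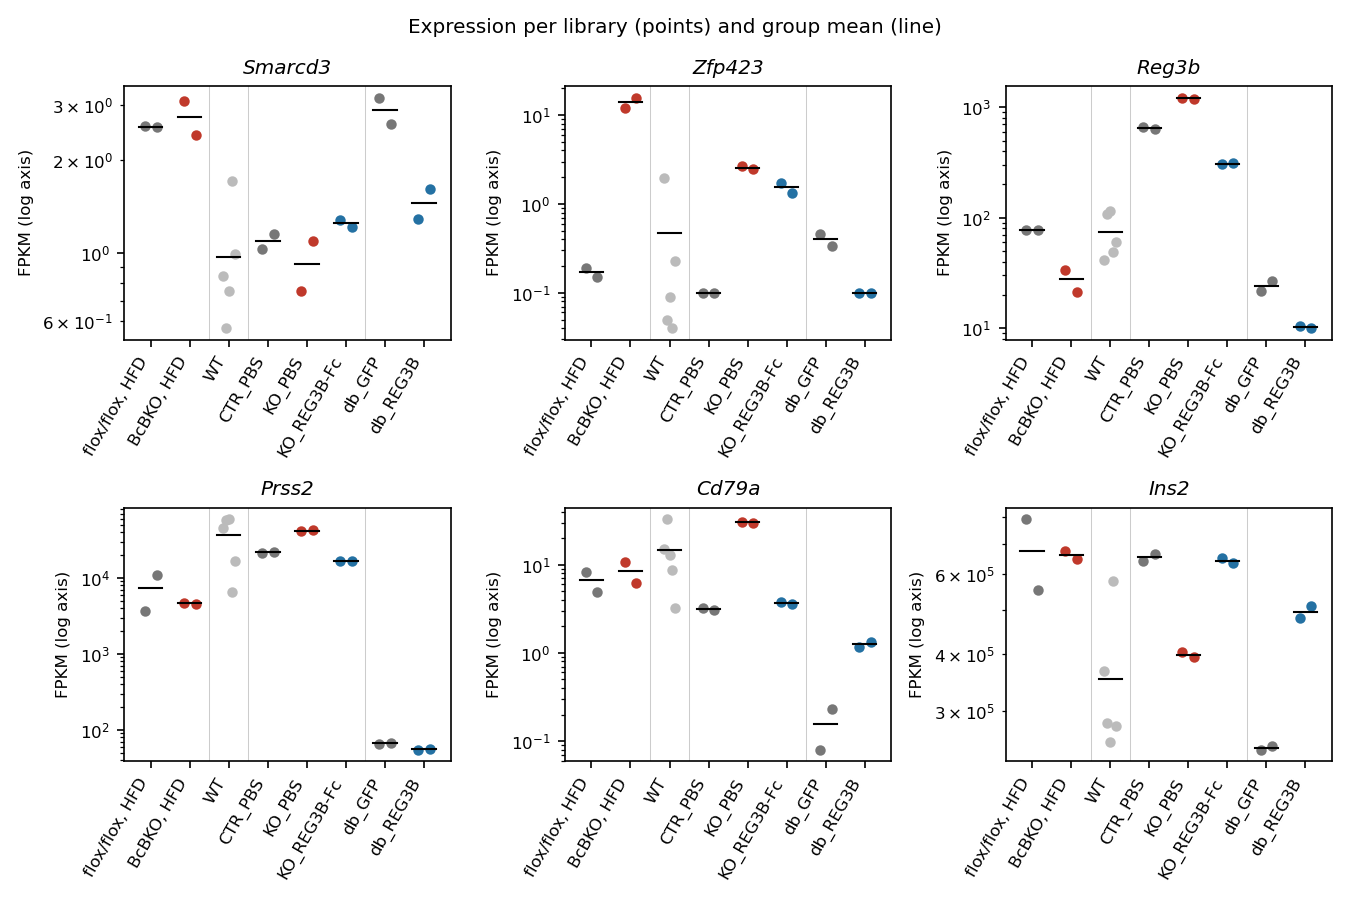
FPKM (vertical log axes) of 6 genes in every library (points) with the group mean (line), by group. Zfp423 lies at 12.1 and 15.8 FPKM in BcBKO and at 0.19 and 0.15 FPKM in flox/flox on HFD, and Cd79a at 30.3 and 29.9 FPKM in KO_PBS against 3.23 and 3.10 FPKM in CTR_PBS.

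The first comparison asked what the ablation changes in islets of mice on HFD. Zfp423 (Entrez 94187, chromosome 8, 87661810 to 87962053), a zinc finger transcription factor known from preadipocytes, rose in BcBKO from 0.170 ± 0.0283 to 13.9 ± 2.63 FPKM (log2 change 3.66, adjusted p = 0.0348). Among genes of at least 5 FPKM, the next largest differences were lower levels of REG3 genes, secreted antimicrobial lectins of the pancreas and gut, and none of them passed the test. Reg3b (Entrez 18489, chromosome 6, 78370885 to 78373466) went from 77.8 ± 0.205 to 27.5 ± 8.80 FPKM (log2 change -1.50, adjusted p = 1.000), Reg3a from 19.0 ± 5.76 to 4.33 ± 1.48 FPKM (log2 change -1.90) and Reg3g from 17.8 ± 5.20 to 3.42 ± 2.83 FPKM (log2 change -2.23). Each of these 3 genes was lower in both BcBKO libraries than in both flox/flox libraries. The authors' table calls all 3, with adjusted p = 1.18e-10 for Reg3b, 1.59e-06 for Reg3a and 0.00557 for Reg3g. With replicate number as a block limma called Reg3a and Reg3g lower (adjusted p = 0.00205 and 0.0421), Ccl5 and Zfp423 higher (0.0183 and 0.000912) and not Reg3b (0.0609). The labels do not pair the libraries, although the replicate differences of the HFD groups correlated at 0.669.

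Other genes were higher in both BcBKO libraries without passing limma's test. Ccl5, a T cell attractant, measured 3.48 ± 0.863 to 11.0 ± 1.28 FPKM, Stmn1, a microtubule regulator of dividing cells, 7.85 ± 1.12 to 14.8 ± 1.01 FPKM, and Th, the first enzyme of catecholamine synthesis, 11.9 ± 1.60 to 21.2 ± 0.445 FPKM. Ffar2, a receptor for short-chain fatty acids, was lower in both (from 11.2 ± 0.198 to 6.71 ± 0.735 FPKM, log2 change -0.67). The authors' table calls Ccl5, Th and Ffar2 (adjusted p = 0.0432, 0.0121 and 0.00495). The hormone genes barely moved, with log2 changes after median scaling of -0.06 for Ins1, -0.10 for Ins2 and -0.28 for the glucagon gene Gcg, none passing. Trypsinogen Prss2 measured 3689 and 11021 FPKM in flox/flox against 4677 and 4534 FPKM in BcBKO, so a single flox/flox library set its log2 change of -0.47.

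As groups, 11 of the 22 lists passed camera on HFD although 0 of their members passed over all genes. With an estimated correlation 0 lists passed, at adjusted p = 0.539 for the REG, dedifferentiation, endothelial, interferon, unfolded protein, oxidative phosphorylation and proliferation lists, 0.597 for the acinar, cholesterol and apoptosis lists, and 0.614 for the stellate list. That setting leaves 2 degrees of freedom here, and the unfolded protein call was lost at an estimated correlation of 0.00325, below the preset 0.01. Only the REG, endothelial and interferon lists kept call and direction whichever library was left out, and their medians still ranged from -1.62 to -0.741, 0.201 to 0.390 and 0.213 to 0.711. Relative to the median gene, the REG family was lower (median -1.25, adjusted p = 2.93e-12), with 0 of 6 members passing over all genes and 3 lower adjusted over the list alone. The acinar list was lower (-0.42, adjusted p = 4.46e-07, with Prss1 higher as the only passing member adjusted over the list alone). That direction rested on flox/flox replicate 2, the library with 9.55% acinar transcripts, and without it the acinar list pointed up (0.402, camera adjusted p = 4.90e-09). Interferon response genes such as Isg15, 2.21 ± 0.0424 to 3.72 ± 0.764 FPKM, were higher (0.47, adjusted p = 2.71e-10). Endothelial genes such as Cdh5, 8.21 ± 0.417 to 11.8 ± 1.17 FPKM, were higher (0.28, adjusted p = 1.42e-07), as were proliferation genes such as Top2a, 1.31 ± 0.601 to 3.67 ± 1.05 FPKM (0.35, adjusted p = 1.73e-06). Cholesterol synthesis (0.18, adjusted p = 0.000109), dedifferentiation (0.57, adjusted p = 0.00662), stellate (0.23, adjusted p = 0.0204) and apoptosis genes (0.16, adjusted p = 0.0215) were higher. Without 1 library the dedifferentiation median ranged from 0.139 to 0.706 and the stellate median from -0.0656 to 0.793. Rescaled to an equal sum with all genes kept, the stellate call was lost (camera adjusted p = 0.06), and without acinar and REG genes it was kept (0.00437). The dedifferentiation list had 4 members higher adjusted over the list alone, among them Cck, a gut hormone gene, at 0.395 ± 0.163 to 3.14 ± 1.80 FPKM. In the inflammation list, which did not pass on the deposited scale (adjusted p = 0.164, 0.0319 after median scaling), Ccl5 was higher adjusted over the list alone. Oxidative phosphorylation (-0.09, adjusted p = 0.00301) and unfolded protein response genes (-0.11, adjusted p = 0.0197, 0.127 after median scaling) were lower.

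With replicate number as a block the same 11 lists passed, and the JAK-STAT3 list as well (adjusted p = 0.0316, against 0.830 without the block). The other 11 lists did not pass on the deposited scale on HFD, among them beta cell identity (median 0.01, adjusted p = 0.316), immune cell (0.10, adjusted p = 0.165) and SWI/SNF subunits (-0.03, adjusted p = 0.725). Single libraries decided some of these as well. Without flox/flox replicate 2 the beta cell identity list passed camera as lower (-0.152, adjusted p = 0.0238) and the immune list as higher (0.393, 4.64e-08), and without flox/flox replicate 1 the immune list passed as lower (-0.187, 0.0185). In all, limma called 1 gene higher and 0 lower among 11560, with 427 genes (3.69%) at an unadjusted p under 0.05, and the authors' table calls 13 higher and 6 lower among the same genes. Groups did not overlap for 30.1% of genes, where chance gives 33.3% if libraries vary independently. Replicate differences of the HFD groups correlated at 0.669, so 33.3% is not a firm baseline here. No absence of an effect is read from this share or from the 3.69%. With any 1 of the 4 libraries left out limma called 0 genes, a test of 1 library against 2 with 1 residual degree of freedom. Zfp423 still changed by 3.69 and 3.64 without flox/flox replicates 1 and 2 (adjusted p = 0.522 and 0.614), and fell under the filter on low values without either BcBKO library. The beta cell identity median and mean differed in sign, as did those of the antioxidant list.

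The second comparison asked what the knockout changed in the islets labelled PBS, where the labels do not say how PBS was given. KO_PBS islets held more transcripts of exocrine, immune and connective tissue, and less of several beta cell genes. The median gene was lower by -0.438 on the log2 scale, so the changes and list counts below are relative to it (median scaling), while list tests stay on the deposited scale. All 26 acinar genes rose on both scales, by a median of 1.45, among them Prss2 (21608 ± 683 to 41756 ± 1457 FPKM, log2 change 1.48, adjusted p = 4.67e-07) and Try4 (1.61). All 6 REG genes rose on both scales, by a median of 1.43. Reg3b went from 651 ± 23.6 to 1204 ± 32.5 FPKM (log2 change 1.42, adjusted p = 1.01e-07), Reg3g changed by 1.60, Reg1 by 1.56 and Reg3a by 1.44. The acinar list's adjusted p was 3.6e-52, or 0.00926 with an estimated correlation, and the REG family's was 2.1e-13, or 0.0290 with an estimated correlation.

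Among genes of at least 5 FPKM in KO_PBS, Cd79b and the myeloid lysozyme Lyz2 had the largest rises, in the libraries where acinar transcripts were also higher. Cd79b and Cd79a, the signalling chains of the B cell receptor, went from 0.120 ± 0.0707 to 10.2 ± 0.841 FPKM and from 3.17 ± 0.0919 to 30.1 ± 0.233 FPKM, log2 changes of 3.70 and 3.38 (adjusted p = 3.5e-08 and 1.11e-08). The B cell surface gene Ms4a1 (3.03, listed at 0 in CTR_PBS) rose with them, as did Cd37 (3.40), Ly6d (3.37), Fcmr (3.12) and the antigen presentation gene H2-DMb2 (3.27). Lyz2 went from 10.8 ± 0.615 to 91.7 ± 3.94 FPKM (3.48). All 17 tested immune genes rose after median scaling and 16 on the deposited scale, 17 adjusted over the list alone (adjusted p = 1.19e-30, or 0.0290 with an estimated correlation). In the stellate and matrix list 9 of 11 rose and none fell, 10 higher adjusted over the list alone, with the collagens Col1a1 (2.11) and Col3a1 (1.92) and the proteoglycan Dcn (1.88; list adjusted p = 4.43e-13, or 0.0290 with an estimated correlation). On the deposited scale 8 rose and 2 fell in that list.

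Inflammation genes rose in 10 of 11 cases and fell in 1 (9 and 1 on the deposited scale), the same counts adjusted over the list alone, with the adhesion molecule Vcam1 (2.21), Ccl5 (1.81) and the iron-binding lipocalin Lcn2 (1.75; adjusted p = 4.13e-13, or 0.0290 with an estimated correlation). Proliferation genes rose in 14 of 18 cases and fell in 2 (9 and 4 on the deposited scale), 14 higher and 2 lower adjusted over the list alone, with Top2a (1.39) and Birc5 (1.24) up and the beta cell cyclin Ccnd2 (-0.61) down (adjusted p = 1.36e-10, or 0.0290 with an estimated correlation). Interferon genes rose in 12 of 14 cases after scaling, against 6 that rose and 3 that fell before, 12 adjusted over the list alone (adjusted p = 7.2e-07), a call lost with adjusted p = 0.0665 with an estimated correlation. Dedifferentiation and disallowed genes rose in 10 of 11 cases (6 rose and 4 fell on the deposited scale), 10 adjusted over the list alone, led by Cck (2.15), the gastrin gene Gast (1.51) and lactate dehydrogenase Ldha (1.22), with adjusted p = 8.3e-06, a call lost at 0.151 with an estimated correlation. Txnip, a glucose-induced inhibitor of thioredoxin, rose from 146 ± 0.431 to 363 ± 11.1 FPKM (1.83).

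Beta cell identity genes fell in 20 of 27 cases and rose in none, 22 lower adjusted over the list alone, and 27 fell on the deposited scale. Insulin took 38.9 and 38.2% of summed FPKM in KO_PBS and 57.5 and 58.4% in CTR_PBS. Median scaling does not separate lower expression in beta cells from a smaller share of beta cell transcripts. Ucn3, a peptide of mature beta cells, fell from 244 ± 1.31 to 88.8 ± 2.51 FPKM (log2 change -0.93), the transcription factor Mafa changed by -0.92, the glucose-6-phosphatase G6pc2 by -0.84 and the channel Trpm5 by -0.84. The list passed camera (adjusted p = 1.72e-05) but not with an estimated correlation (adjusted p = 0.292 with an estimated correlation). Insulin gene Ins1 fell by 0.35 (adjusted p = 0.00419) while Ins2 at -0.18 did not pass after scaling (adjusted p = 0.107), and on the deposited scale they changed by -0.88 and -0.71. Granule exocytosis genes fell in 16 of 20 cases and rose in 1 (19 and 0 on the deposited scale), 16 lower and 1 higher adjusted over the list alone, among them Vamp2 (-0.37), with adjusted p = 0.0102, a call lost at 0.475 with an estimated correlation. The largest falls of single genes were in the matrix protein Spp1 (osteopontin, from 435 ± 12.3 to 80.1 ± 2.68 FPKM, -1.90) and the GABA-forming enzyme Gad1 (from 33.7 ± 0.997 to 9.31 ± 0.233 FPKM, -1.26). Hspb6 (-1.23), Cox6a2 (-1.20), Rgs4 (-1.17) and Angptl7 (-1.08) fell as well. Zfp423 was again higher in KO_PBS (0.10 ± 0 to 2.57 ± 0.141 FPKM, log2 change 2.00, adjusted p = 4.75e-07).

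Markers of other islet and vessel cells did not pass as lists, and their direction depended on the scale. Of 11 other hormone genes 6 rose after scaling, 6 adjusted over the list alone, while 2 rose and 9 fell before scaling, with Gcg at 0.17 after and -0.36 before scaling (list adjusted p = 0.364). Of 10 endothelial genes 7 rose and 2 fell after scaling, the same adjusted over the list alone, and 8 fell before (median 0.21 after scaling, adjusted p = 0.943). Of 6 duct genes 3 rose and 2 fell (2 and 3 before scaling), the same adjusted over the list alone, with Muc1 (1.10) and Krt19 (0.93) up and Spp1 down (adjusted p = 0.202). JAK-STAT3 (8 rose, 2 fell, adjusted p = 0.0956), unfolded protein response (8 rose, 4 fell, adjusted p = 0.602), antioxidant (9 rose, 3 fell, adjusted p = 0.318), oxidative phosphorylation (16 rose, 4 fell, adjusted p = 0.0851), glycolysis (3 rose, 3 fell, adjusted p = 0.318) and cholesterol synthesis lists (5 rose, 4 fell, adjusted p = 0.195) did not pass camera. Nor did lipogenesis (6 rose, 4 fell, adjusted p = 0.196), apoptosis (7 rose, 0 fell, adjusted p = 0.258, but 0.00268 when the test too was run after median scaling) and SWI/SNF subunits (2 rose, 6 fell, adjusted p = 0.114). On the deposited scale most of these genes were lower, with 2, 3, 3, 0, 1, 0, 3, 1 and 0 that rose and 7, 15, 13, 34, 12, 16, 8, 8 and 22 that fell in the 9 lists in the same order. Adjusted over the list alone after scaling, these 9 lists gave 9, 9, 9, 17, 3, 5, 6, 8 and 2 higher and 2, 5, 3, 4, 3, 4, 5, 0 and 6 lower genes in the same order. The median and mean of the unfolded protein list differed in sign, and the oxidative phosphorylation test pointed down where its median lay above the median gene.

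In all, limma called 1021 genes higher and 9603 lower of 11789 on the deposited scale (9.61% of calls higher). After median scaling it called 2905 higher and 2357 lower (55.2% higher), of which 1021 higher and 2357 lower were called on both scales. Rescaled to an equal sum without acinar and REG genes it called 3887 higher and 1237 lower (75.9% higher), so the balance of directions depended on the scale. On that scale the oxidative phosphorylation list passed camera as higher (adjusted p = 0.0152), and with all genes kept the JAK-STAT3 and apoptosis lists passed as higher (0.0263 and 0.0482). The authors' table calls 1813 higher and 1888 lower among these genes. At least a 2-fold change after scaling was seen in 435 higher and 15 lower called genes.

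**Figure D3:**
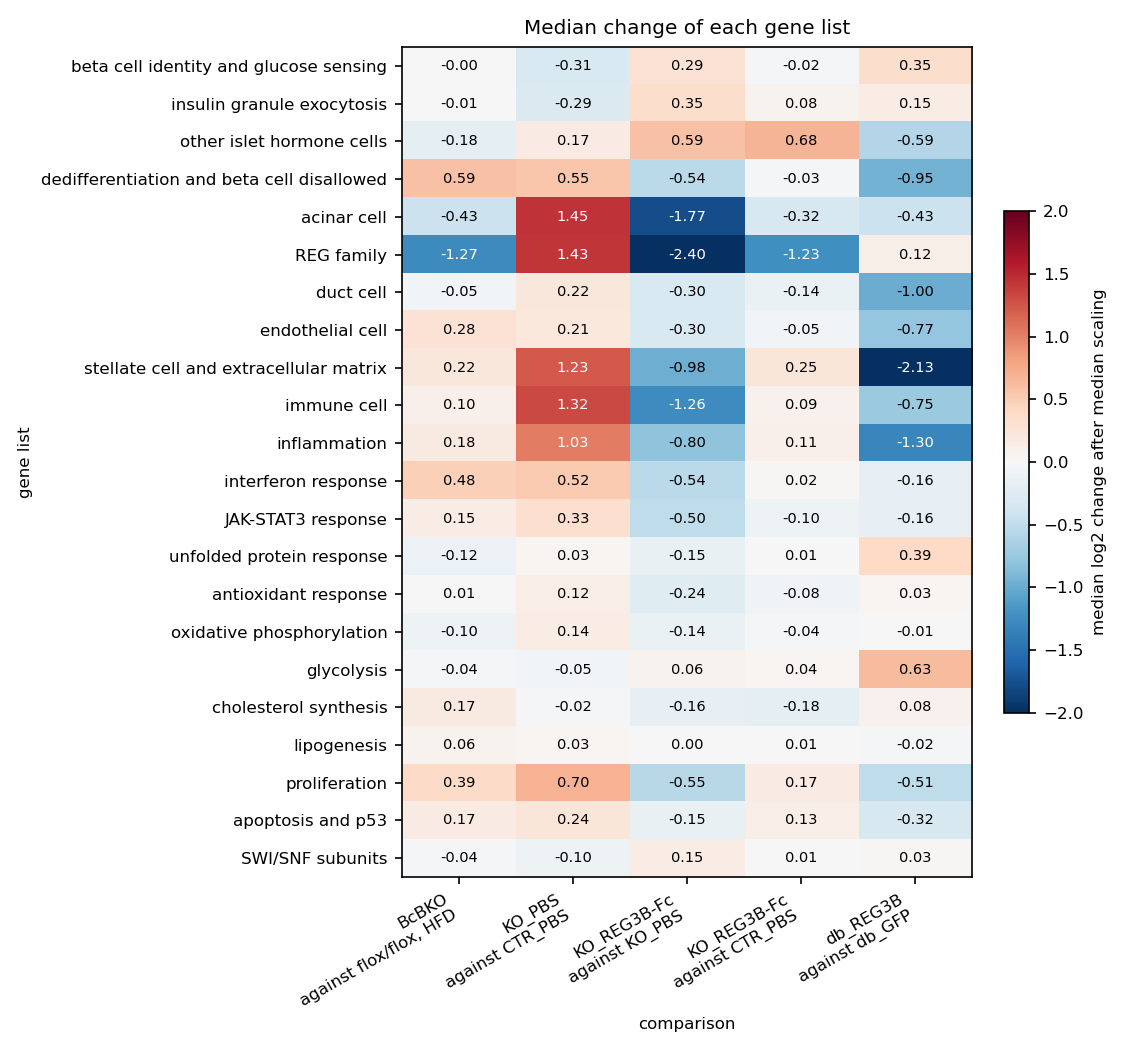
Median log2 change after median scaling (colour and printed value) of each of the 22 gene lists (vertical axis) in the 5 comparisons (horizontal axis). The acinar and REG lists read 1.45 and 1.43 for KO_PBS against CTR_PBS and -1.77 and -2.40 for KO_REG3B-Fc against KO_PBS.

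The third comparison asked what differed with REG3B-Fc in knockout islets. The labels name no library with Fc alone and no control islets with REG3B-Fc. Effects of REG3B and of its Fc part therefore cannot be told apart. Exocrine, immune and matrix transcripts were lower with REG3B-Fc, and other islet hormones higher. The median gene was higher by 0.525 on the log2 scale, and the changes and list counts are relative to it, with list tests on the deposited scale. All 26 acinar genes fell on both scales (median -1.77), with Prss2 going from 41756 ± 1457 to 16664 ± 147 FPKM (log2 change -1.96, adjusted p = 9.15e-08). All 6 REG genes fell on both scales (median -2.40), with Reg3b going from 1204 ± 32.5 to 308 ± 5.69 FPKM (-2.60, adjusted p = 9.89e-09) and Reg3g changing by -2.89. Camera gave adjusted p = 1.2e-68 for the acinar and 2.63e-22 for the REG list, and 0.00610 and 0.0267 with an estimated correlation.

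Genes with large rises in KO_PBS were lower again, Cd79a from 30.1 ± 0.233 to 3.64 ± 0.127 FPKM (-3.31), Cd79b by -3.63, and with them the B cell chemokine Cxcl13 (-3.08). All 17 immune genes fell after scaling (14 fell and 1 rose before, 17 adjusted over the list alone), with adjusted p = 1.18e-29, or 0.0267 with an estimated correlation. Stellate and matrix genes fell in 10 of 11 cases, 11 adjusted over the list alone (Col1a1 -1.48, adjusted p = 8.58e-12, or 0.0335 with an estimated correlation). Inflammation genes fell in 10 cases and rose in 1, the same adjusted over the list alone (Vcam1 -1.87, adjusted p = 6.1e-11, or 0.0317 with an estimated correlation). Proliferation genes fell in 14 of 18 cases and rose in 2, the same adjusted over the list alone (Top2a -0.91, Ccnd2 0.69, adjusted p = 3.19e-08, or 0.0335 with an estimated correlation). On the deposited scale fewer members of these 3 lists fell (8, 7 and 9) and some rose (3, 2 and 7).

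Endocrine genes were higher in the same libraries. Of 11 other hormone genes 9 rose and none fell (11 rose on the deposited scale), 10 higher and 1 lower adjusted over the list alone. The ghrelin gene Ghrl rose from 1.89 ± 0.318 to 8.42 ± 0.240 FPKM (1.23), somatostatin Sst from 1505 ± 106 to 4392 ± 29.3 FPKM (0.91), Gcg from 4662 ± 165 to 12585 ± 359 FPKM (0.80) and pancreatic polypeptide Ppy by 0.79. Beta cell identity genes rose in 22 of 27 cases and fell in none (27 rose on the deposited scale), 23 adjusted over the list alone, with Trpm5 (1.03), Mafa (0.83), the glucose transporter Slc2a2 (0.70) and Ucn3 (0.68). Insulin took 58.1 and 57.7% of summed FPKM in KO_REG3B-Fc and 38.9 and 38.2% in KO_PBS. A larger share of beta cell transcripts and higher expression in beta cells cannot be told apart here either. Ins1 (0.09, adjusted p = 0.340) and Ins2 (0.05, adjusted p = 0.617) did not pass after scaling, but rose on the deposited scale (0.72 and 0.69, adjusted p = 8.67e-07 and 1.55e-06). Granule exocytosis genes rose in 18 of 20 cases (20 on the deposited scale), 18 adjusted over the list alone (Chga 0.46). The calls of these 3 lists (adjusted p = 0.0241, 4.7e-05 and 0.00168) were lost with an estimated correlation, at adjusted p = 0.196, 0.292 and 0.334 with an estimated correlation. Gad1 (1.21), Cox6a2 (1.53), Ppp1r1a (0.99) and Angptl7 (1.13) rose, while Zfp423 fell from 2.57 ± 0.141 to 1.53 ± 0.290 FPKM (-0.93, adjusted p = 3.59e-05).

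Interferon genes fell in 14 of 14 cases after scaling, 14 adjusted over the list alone (adjusted p = 5.57e-08, 0.0528 with an estimated correlation), against 5 that fell and 2 that rose before. Dedifferentiation genes fell in 9 cases and rose in 1 (3 and 3 before scaling), the same adjusted over the list alone (adjusted p = 4.86e-06, 0.143 with an estimated correlation). JAK-STAT3 genes fell in 10 cases and rose in 3 (3 fell and 6 rose before scaling), the same adjusted over the list alone (adjusted p = 0.00186, 0.346 with an estimated correlation), and duct genes fell in 3 and rose in 2 (2 fell and 4 rose before scaling), the same adjusted over the list alone (adjusted p = 0.0389, 0.316 with an estimated correlation, 0.112 after median scaling). Antioxidant, oxidative phosphorylation and cholesterol synthesis lists did not pass on the deposited scale (adjusted p = 0.0545, 0.0802 and 0.978) and passed as lower after median scaling (0.00233, 0.00632 and 0.00632). Their members rose in 12, 35 and 15 cases and fell in 5, 0 and 0 on the deposited scale, and rose in 2, 3 and 1 and fell in 11, 17 and 9 after scaling. In all, limma called 10157 genes higher and 822 lower on the deposited scale (92.5% higher) and 2376 higher and 2917 lower after median scaling (44.9% higher; 2391 and 2762 without acinar and REG genes), with 2376 higher and 822 lower on both scales. The authors' table calls 1691 higher and 1829 lower among these genes. The test and median of the oxidative phosphorylation list differed in sign, as did the median and mean of the lipogenesis list.

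Set side by side, changes of KO_REG3B-Fc against KO_PBS ran opposite to those of KO_PBS against CTR_PBS across 11789 genes (Pearson r = -0.907, Spearman -0.838, on the deposited scale, as for the other correlations below). Both comparisons share the KO_PBS libraries with opposite sign, and 100 simulations of unchanged groups gave r = -0.499 from that alone. The covariance was -0.155 against -0.00320 in the simulations. These held replicate spread only, so they cannot tell a REG3B-Fc effect from a shift of the KO_PBS libraries alone. Acinar transcripts took 40.2 and 41.4% in KO_PBS, against 19.8 and 19.6% in CTR_PBS and 17.0 and 17.2% in KO_REG3B-Fc. After median scaling 2361 genes were called higher in KO_PBS and lower with REG3B-Fc and 1594 the other way round, where independent lists share 719 and 475. In the same direction 32 genes were called higher in both and 29 lower in both, where independent lists share 585 and 583. Part of these differences may come from the shared KO_PBS libraries, which favour opposite calls and are too few to split.

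**Figure D4:**
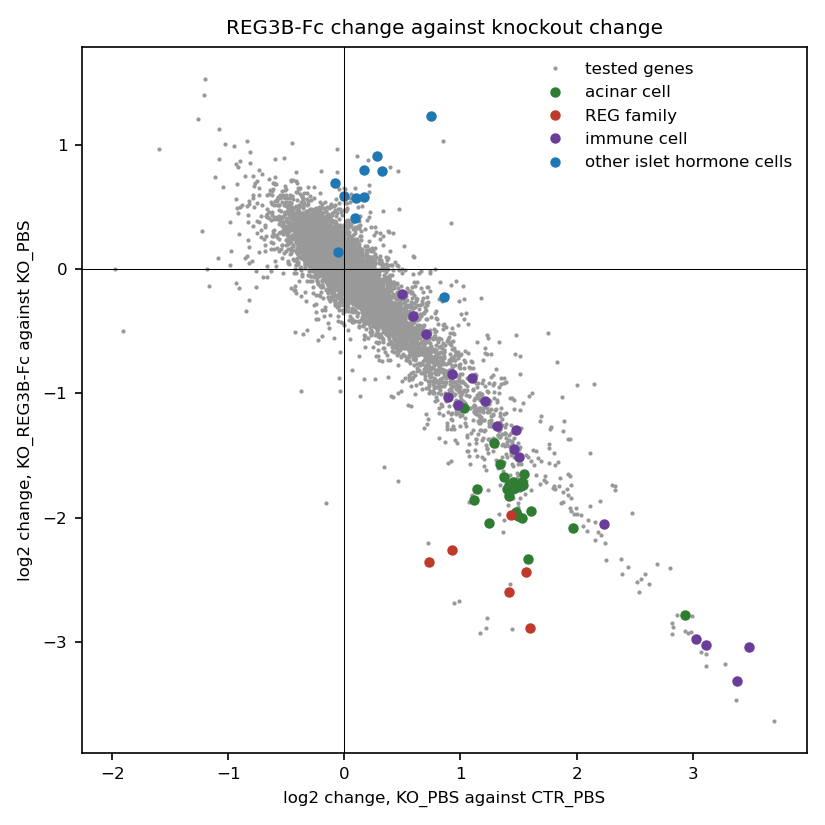
Log2 change after median scaling for KO_REG3B-Fc against KO_PBS (vertical axis) and for KO_PBS against CTR_PBS (horizontal axis), 1 point per tested gene, with 4 gene lists in colour. The axes share the KO_PBS libraries, and the points run from upper left to lower right (r = -0.907 for the changes on the deposited scale).

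How far treated knockout islets stood from controls was read from KO_REG3B-Fc against CTR_PBS, where the median gene moved by 0.0859 and changes are on the deposited scale. Other islet hormones were higher and REG genes lower than in controls. All 11 other hormone genes rose (10 after scaling, 11 adjusted over the list alone), with Ghrl (1.17 ± 0.0212 to 8.42 ± 0.240 FPKM, log2 change 2.12), Sst (1.30), Ppy (1.22) and Gcg (5978 ± 83.6 to 12585 ± 359 FPKM, 1.07), and the list passed with adjusted p = 2.66e-13, or 0.0304 with an estimated correlation. All 6 REG genes fell on both scales, with Reg2 (1839.5 ± 68.8 to 637 ± 17.6 FPKM, -1.53), Reg3g (-1.19) and Reg3b (651 ± 23.6 to 308 ± 5.69 FPKM, -1.08, adjusted p = 6.5e-07; list adjusted p = 2.33e-23, or 0.0304 with an estimated correlation). Acinar genes fell in 17 of 26 cases, 19 adjusted over the list alone, by a smaller median of -0.30 relative to the median gene (Prss2 -0.37; adjusted p = 3.45e-26, or 0.0262 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 18 cases, 3 adjusted over the list alone (Msmo1 -0.22; adjusted p = 1.78e-08, or 0.0424 with an estimated correlation).

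Single genes that stayed apart from controls included Spp1, which fell from 435 ± 12.3 to 87.8 ± 0.870 FPKM (-2.30), the antibody joining chain Jchain (-1.72), the haemoglobin genes Hba-a2 (-1.65) and Hbb-bs (-1.48) and the acute phase gene Lrg1 (-1.42). Lcn2 (1.36), the retinol carrier Rbp4 (1.31), Txnip (1.19) and the pyruvate dehydrogenase kinase Pdk4 (1.06) rose. Stat3, the transcription factor downstream of interleukin 6 type receptors, fell from 39.0 ± 0.679 to 21.4 ± 0.339 FPKM (-0.84). Zfp423 stayed higher than in controls (0.10 ± 0 to 1.53 ± 0.290 FPKM, 1.20, adjusted p = 4.05e-05), while Ins2 (-0.02, adjusted p = 0.781) did not pass. Ins1 passed on the deposited scale (-0.16, adjusted p = 0.0452) and not after median scaling (adjusted p = 0.0505). Immune (8 rose, 12 adjusted over the list alone, adjusted p = 0.00864), stellate (7 rose, 8 higher and 1 lower adjusted over the list alone, adjusted p = 0.00609) and proliferation lists (9 rose, 12 adjusted over the list alone, adjusted p = 0.0135) passed camera and were lost at adjusted p = 0.291, 0.265 and 0.254 with an estimated correlation. Granule exocytosis, duct, antioxidant and apoptosis lists passed in the same way (adjusted p = 0.00864, 0.00864, 0.0156 and 0.0476) and were lost at adjusted p = 0.446, 0.291, 0.346 and 0.291 with an estimated correlation, and the apoptosis list also with a replicate block (adjusted p = 0.0656). The inflammation list did not pass on the deposited scale (adjusted p = 0.101) and passed as higher after median scaling (0.0245). Rescaled to an equal sum with all genes kept, the inflammation list passed as higher and the JAK-STAT3 list as lower (adjusted p = 0.0470 and 0.0299), and the proliferation and apoptosis calls were lost (0.0628 and 0.0584). Without acinar and REG genes the inflammation and JAK-STAT3 lists did not pass camera (adjusted p = 0.0795 and 0.0683). The proliferation and apoptosis calls were kept on that scale (0.0103 and 0.0447). Here limma called 1977 genes higher and 338 lower (85.4% higher) and, after median scaling, 645 higher and 625 lower (50.8% higher). The count fell to 890 and 803 without CTR_PBS replicates 1 and 2, and to 980 and 1250 without KO_REG3B-Fc replicates 1 and 2. The authors deposited no such comparison. Median, mean and test did not share a sign for the beta cell identity, dedifferentiation, interferon, unfolded protein, oxidative phosphorylation and lipogenesis lists, none of which passed.

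The last comparison asked what REG3B changed in db islets, with GFP as control. Labels do not say how either was delivered, and db is taken as the diabetic, leptin receptor deficient db strain. Insulin and several beta cell transcripts were higher with REG3B, and inflammation, matrix and dedifferentiation genes lower. Ins1 rose from 77952 ± 1148 to 156580.0 ± 7767 FPKM (log2 change 1.01, adjusted p = 1.02e-06) and Ins2 from 248990.0 ± 3634 to 495360.0 ± 21493 FPKM (0.99, adjusted p = 2.23e-06). Beta cell identity genes rose in 18 of 27 cases and fell in 2, 18 higher and 3 lower adjusted over the list alone, with Mafa (129 ± 5.15 to 397 ± 3.37 FPKM, 1.61), Trpm5 (1.58) and Slc2a2 (49.1 ± 0.113 to 137 ± 3.93 FPKM, 1.46; adjusted p = 1.49e-10, 0.324 with an estimated correlation). Among the largest rises were the heat shock genes Hspa1a (8.10 ± 0.156 to 75.7 ± 4.21 FPKM, 3.07) and Hspa1b (2.99) and haem oxygenase Hmox1 (1.67). Hspa1a differed widely between replicates on HFD, at 576 and 38.8 FPKM in flox/flox and 670 and 63.0 FPKM in BcBKO. Unfolded protein response genes rose in 17 of 20 cases, 17 adjusted over the list alone (Sdf2l1 0.71, Ddit3 0.57; adjusted p = 4.8e-13, 0.269 with an estimated correlation). Glycolysis genes rose in 13 of 15 cases and fell in 2, the same adjusted over the list alone (Tpi1 0.86, Pgk1 0.82; adjusted p = 4.16e-10, 0.324 with an estimated correlation).

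Inflammation genes fell in 14 of 15 cases and rose in 1, the same adjusted over the list alone, with Lcn2 (274 ± 9.69 to 15.3 ± 0.00707 FPKM, -4.08, adjusted p = 1.91e-10), the monocyte chemokine Ccl2 (13.3 ± 0.757 to 0.110 ± 0 FPKM, -3.68) and serum amyloid Saa3 (-3.42; list adjusted p = 3.51e-07, 0.269 with an estimated correlation). Lrg1 (45.3 ± 0.127 to 0.655 ± 0.0354 FPKM, -4.81), the neuropeptide galanin Gal (-4.11), the metalloproteinase Mmp7 (-3.28) and the matrix protein Tnc (-3.27) fell with them. Stellate and matrix genes fell in 14 of 15 cases, 14 adjusted over the list alone (Col1a1 377 ± 6.22 to 60.1 ± 2.69 FPKM, -2.63; adjusted p = 8.28e-13, 0.269 with an estimated correlation). Dedifferentiation genes fell in 10 of 11 cases, 10 adjusted over the list alone (Cck 73.6 ± 1.19 to 9.15 ± 1.44 FPKM, -2.88, Gast -2.76, the progenitor factor Sox9 -1.59; adjusted p = 4.51e-05, 0.269 with an estimated correlation). Other hormone genes fell in 9 of 11 cases, 9 adjusted over the list alone, with Gcg (40837 ± 550.3 to 21453 ± 179 FPKM, -0.93; adjusted p = 0.000183, 0.269 with an estimated correlation). Chgb, a granule protein of endocrine cells, fell by 1.09.

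Markers of non-endocrine cells were lower in the same db_REG3B libraries. All 11 endothelial genes fell, 11 adjusted over the list alone (adjusted p = 8.5e-06, 0.324 with an estimated correlation). Immune genes fell in 15 of 16 cases and rose in 1, the same adjusted over the list alone (Lyz2 -1.18; adjusted p = 7.41e-06, 0.269 with an estimated correlation). Duct genes fell in 5 of 6 cases, 5 adjusted over the list alone (Spp1 958 ± 6.53 to 288 ± 9.49 FPKM, -1.73; adjusted p = 0.000486, 0.358 with an estimated correlation), and acinar genes in 18 of 25 with 3 rising, the same adjusted over the list alone (adjusted p = 0.000486, 0.341 with an estimated correlation). In the REG family Reg3b (24.1 ± 3.37 to 10.2 ± 0.304 FPKM, -1.16, adjusted p = 6.75e-06) and Reg1 (-0.74) fell and Reg3a (0.810 ± 0.424 to 2.12 ± 0.544 FPKM, 0.80) rose. The median of that list lay above the median gene and its mean and test below (adjusted p = 0.758). Proliferation genes fell in 15 of 21 cases and rose in 2, 16 lower adjusted over the list alone (Top2a -0.86; adjusted p = 0.00459, 0.269 with an estimated correlation). Granule exocytosis, JAK-STAT3 and cholesterol synthesis lists passed camera (adjusted p = 0.000723, 0.0451 and 0.0310) and were lost at adjusted p = 0.386, 0.496 and 0.520 with an estimated correlation. With a replicate block the JAK-STAT3, cholesterol and proliferation calls were lost (adjusted p = 0.250, 0.0771 and 0.0958).

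In all, limma called 1530 genes higher and 3856 lower of 12507 in the db table (28.4% higher), and 2590 higher and 3203 lower after median scaling (44.7% higher), with 1530 higher and 3203 lower on both scales. The deposited values summed to 934094 and 944121 in db_GFP and to 1173344 and 1203951 in db_REG3B. Rescaled to an equal sum, with all genes kept, limma called 292 higher and 10428 lower (2.72% higher), and the median gene changed by -0.366. On that scale beta cell identity genes rose in 12 and fell in 12 of 27 cases (median -0.0618), unfolded protein genes rose in 6 and fell in 4 of 20, and Ins1 and Ins2 still rose (0.67 and 0.65). Granule exocytosis genes rose in 2 and fell in 15 of 20, and the camera calls of the granule exocytosis, JAK-STAT3, cholesterol and proliferation lists were lost (adjusted p = 0.150, 0.0780, 0.164 and 0.239), while the oxidative phosphorylation list passed as lower (0.00538). The authors' table calls 2066 higher and 2232 lower among these genes. A change of at least 2-fold after scaling was seen in 43 higher and 592 lower called genes. The count was 3147 without db_GFP replicate 1 and 3146 without db_GFP replicate 2.

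Changes were then compared between tables that share no library. The REG3B changes in knockout and in db islets correlated across 11454 genes (Pearson r = 0.503, Spearman 0.391). After median scaling 886 genes were called higher in both, where independence gives 523, and 1312 lower in both, where independence gives 590. In opposite directions 261 and 378 genes were called, where independence gives 521 and 592. The insulin share was higher with REG3B in both tables, and the acinar, immune and stellate lists lower. Insulin took 58.1 and 57.7% against 38.9 and 38.2% in knockout, and 54.7 and 55.0% against 34.6 and 35.0% in db libraries. A shared REG3B response and a like shift in cell composition cannot be told apart here. The knockout changes on HFD and in the PBS table correlated weakly across 11074 genes (r = 0.224, Spearman 0.210), and r turned to -0.0355 without flox/flox replicate 1 on HFD. Zfp423 was the only gene called higher in both on the deposited scale, where independence gives 0.0705. By the authors' own calls, 10 genes were higher in both, where independence gives 1.68, and 3 lower in both, where independence gives 0.993. Another 3 were lower on HFD and higher in KO_PBS, namely Reg3a, Reg3b and Reg3g, where independence gives 0.839.

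The 5 WT libraries form a group without a contrast. Ins1 measured 85280 ± 13900 FPKM (SD, n = 5), Ins2 352600 ± 134000 FPKM, Gcg 13920 ± 12200 FPKM (8561 FPKM without replicate 4), Sst 3207 ± 1680 FPKM and Ppy 4038 ± 2510 FPKM. Smarcd1 measured 4.39 ± 1.54 FPKM, Smarcd2 13.2 ± 2.25 FPKM and Smarcd3 0.972 ± 0.440 FPKM. In the REG family Reg1 measured 4921 ± 2940 FPKM, Reg2 282 ± 216 FPKM, Reg3a 18.5 ± 17.5 FPKM, Reg3b 74.9 ± 34.6 FPKM, Reg3d 96.0 ± 32.6 FPKM and Reg3g 16.9 ± 15.6 FPKM. Replicates 4 and 5 list 15278 and 15414 genes where the others list 15518, and the labels do not say whether all 5 were processed alike. The CV ran from 16.3% for Ins1 to 94.3% for Reg3a among these genes. Acinar transcripts took 36.6 ± 18.6% of summed FPKM, from 6.95 to 53.4%, other hormone genes 2.05 ± 1.55%, immune genes 0.0384 ± 0.00973%, duct genes 0.0145 ± 0.00421%, endothelial genes 0.0131 ± 0.00452% and stellate genes 0.0103 ± 0.00398%.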

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

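All tests in this part were chosen after the result was seen, except the test on the genes around Zfp423, whose prediction was written before its result.

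Single WT libraries stood far from the other 4, with the gap to the nearest library given as a share of the whole range. In WT replicate 4 this share was 0.799 for Iapp (58759 FPKM), 0.816 for Gcg (35363 FPKM), 0.725 for Ppy (8380.1 FPKM) and 0.720 for the other islet hormone share (4.72%). In WT replicate 1 it was 0.901 for Zfp423 (1.95 FPKM). Chance gives such a gap in about 1 in 20 groups, and 25 items were looked at. Replicate 4 lists 15278 genes where replicate 1 lists 15518, so a difference in processing stays open. Replicate 5, with 15414 genes listed, was not set apart in these items. Replicate 4 also held the lowest acinar share, 6.95% against 32.5 to 53.4% in the others, and the highest insulin share, 59.0%. Acinar content was not tested as a source of its gaps. Effects ran in opposite directions between tables for 3 REG genes of the knockout, after median scaling. Reg3a changed by -1.98 on HFD and 1.44 in the PBS table, Reg3b by -1.59 and 1.42, and Reg3g by -2.30 and 1.60. The change with REG3B-Fc in knockout islets and with REG3B in db islets was 0.80 and -0.86 for Gcg, and -1.98 and 0.84 for Reg3a. These differences between tables were not tested.

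KO_PBS libraries held more acinar, REG, immune and stellate transcripts than CTR_PBS libraries. More exocrine tissue carried along with the pooled KO_PBS islets is a candidate source of the acinar part, since 22 of 22 acinar genes with at least 100 FPKM were higher by a median of 1.46 with an SD of 0.154, and the 27 acinar genes are in 0 other lists. That test covers acinar genes only. Over all tested members on the deposited scale, immune and stellate genes changed less evenly (SD 1.03 and 0.745) than acinar genes (SD 0.35). The tables argue against a smaller share of beta cells raising every other cell type alike, as the lower quartile of the acinar list was 1.38 and the upper quartiles of the endothelial and other hormone lists were 0.308 and 0.303. As a set, 57 of these genes argue against a like-sized knockout effect on every diet and treatment, provided BcBKO and KO name the same gene. Their median change was -0.221 on HFD (SD 0.566, -0.918 to 0.385 without 1 library) against 1.44 in the PBS table. The lists did not move alike on HFD, with medians of -0.428 (acinar), -1.27 (REG), 0.1 (immune) and 0.221 (stellate). Immune and stellate medians thus kept the direction of the PBS table, and no conclusion is drawn for them alone. An effect of the knockout without REG3B-Fc stays open and untested, while KO_REG3B-Fc libraries with the same label held 17.0 and 17.2% acinar transcripts against 19.8 and 19.6% in CTR_PBS.

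Zfp423 was far higher in the BcBKO and KO_PBS libraries. The tables argue against a raised chromosomal neighbourhood, as the larger of the median changes of its neighbours was 0.0679 (SD 0.395), over 9 tested in the PBS table. None of the 8 tested on HFD and in the PBS table was higher by 1 or more in both (0 of 8), and Snx20, at 1.05 in the PBS table, was not tested on HFD. DNA of another strain kept around the targeted gene stays open, as Zfp423 lies on chromosome 8 and Smarcd3 on chromosome 5 but the labels do not state which gene was targeted. An effect of the cre transgene or its insertion and an effect of the ablation stay open, and no library with cre alone is named in the labels. WT replicate 1, which carries no knockout label, also reached 1.95 FPKM, against 0.04 to 0.23 FPKM in the other WT libraries. KO_PBS libraries held 2.67 and 2.47 FPKM and KO_REG3B-Fc libraries 1.74 and 1.33 FPKM. The source of the WT value was not tested.

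REG family changes were set against acinar content in the 4 comparisons where the REG list passed. They went with it in KO_PBS against CTR_PBS, departed from it in KO_REG3B-Fc against CTR_PBS, and were undecided in the other comparisons. In KO_PBS against CTR_PBS the REG median minus the acinar median was -0.0275 (1.43 and 1.45, acinar SD 0.345, -0.0705 to 0.0169 without 1 library), so acinar content is a candidate explanation there. In KO_REG3B-Fc against CTR_PBS the difference was -0.918 (-1.23 and -0.316, SD 0.222, -0.919 to -0.905 without 1 library), which argues against acinar content as the whole cause. Acinar content stays open on HFD, where it was -0.837 (-1.27 and -0.428, SD 0.345, -1.51 to -0.148 without 1 library), and in KO_REG3B-Fc against KO_PBS, where it was -0.631 (-2.40 and -1.77, SD 0.300, -0.678 to -0.579). A direct effect of REG3B-Fc or of the ablation on REG expression stays open and was not tested.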

How the results depend on the processing

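TPM in place of FPKM, rescaling to an equal sum with all genes or without acinar and REG genes, and list tests after median scaling or without 1 library were chosen after seeing the data. With an estimated correlation 0, 6, 6, 4 and 0 lists passed (HFD, KO_PBS, KO_REG3B-Fc against KO_PBS, KO_REG3B-Fc against CTR_PBS, db), against 11, 10, 13, 11 and 15 with camera, and with fry 0 passed on HFD, 22 for KO_PBS and 17 for KO_REG3B-Fc against CTR_PBS. The estimated correlation also leaves only 2 or 3 degrees of freedom, so its fewer calls need not reflect correlated members. Unlike camera, fry does not compare a list with other genes, so its calls include the shift of the median gene (-0.438 for KO_PBS). In KO_PBS fry pointed down and camera up for the other hormone, duct, endothelial, JAK-STAT3, unfolded protein, antioxidant, lipogenesis and apoptosis lists. Without 1 library 7 to 11 lists passed on HFD. Median scaling gave 5262, 5293 and 1270 genes in the 3 comparisons of the PBS table, and an equal sum without acinar and REG genes 5124 and 5153 for KO_PBS and KO_REG3B-Fc against KO_PBS and 10710 for db. With all genes kept it gave 10720 for db, so leaving those genes out was not the cause there, and 3641 for KO_REG3B-Fc against CTR_PBS. Replicate number as a block gave 4 genes on HFD. Replicate differences correlated at 0.669 between the HFD groups and at 0.0243, 0.0472, -0.0228 and -0.0499 between groups of the PBS and db tables. Leaving out 1 library, the lone library of a group being assumed to vary like the others, gave 0 to 0 genes on HFD, 803 to 1250 for KO_REG3B-Fc against CTR_PBS and 3146 to 4902 for db. The REG3B-Fc and knockout effects correlated at -0.838 by Spearman and -0.889 for genes above the median of mean expression. The REG3B effects in knockout and db correlated at 0.391 and 0.449, and at 0.492 to 0.503 without 1 library. The knockout effects on HFD and PBS correlated at 0.0522 for genes above the median of mean expression, and at -0.0355 to 0.384 without 1 library.

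Direction turned for few named genes. Median scaling gave -0.056 for Ins1 on HFD, 0.14 for Smarcd3 and 0.17 for Gcg in KO_PBS, and -0.10 for Smarcd3 in KO_REG3B-Fc against KO_PBS. An equal sum without acinar and REG genes gave 0.19 for Smarcd3 and 0.26 for Gcg in KO_PBS, and -0.0903 for Smarcd3 in KO_REG3B-Fc against KO_PBS, and TPM gave 0.029 for Ins2 on HFD. With all genes kept an equal sum gave 0.019 for Ins2 on HFD and 0.027 in KO_REG3B-Fc against CTR_PBS. Without 1 library the HFD changes ran from -0.066 to 0.21 for Smarcd3, -0.14 to 0.21 for Ins1, -0.26 to 0.26 for Ins2, -0.44 to 0.060 for Gcg and -1.26 to 0.32 for Prss2. They ran from -0.26 to 0.00059 for Smarcd3 in KO_PBS and from -0.052 to 0.0061 for Ins2 in KO_REG3B-Fc against CTR_PBS. For all of these the cause was not tested, apart from the fewer libraries where 1 was left out. Count-based normalization and tests were not run for want of counts, fits of only the 2 groups do not apply to the HFD and db tables, and the chow, diet and interaction results had no values. Depth is unknown, so its limit was not assessed.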

Other observations

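Gene groups that did not pass the list test on the deposited scale still held single genes past the threshold in several comparisons. SWI/SNF subunits, the chromatin remodelling complex that BAF60C belongs to, rose in 11 of 24 cases and fell in 3 with REG3B-Fc in knockout islets after median scaling, against 23 and 0 on the deposited scale (adjusted p = 0.0981 by limma's camera on the deposited scale, 0.0361 after median scaling). In db islets with REG3B 2 rose and 5 fell, 5 and 5 after median scaling, and 0 and 20 when rescaled to an equal sum (adjusted p = 0.714). Apoptosis and p53 genes rose in 4 and fell in 9 of 15 cases in db islets with REG3B, 1 and 11 at an equal sum (adjusted p = 0.714). Interferon response genes fell there in 7 of 14 cases and rose in 0, 13 and 0 at an equal sum (adjusted p = 0.133), and oxidative phosphorylation genes fell in 10 of 36 and rose in 2, turning to 4 and 8 after median scaling and to 36 and 0 at an equal sum (adjusted p = 0.714 on the deposited scale and 0.00538 at an equal sum, where the list passed as lower).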
